A study of Mus musculus with 6 samples.

How the data were processed

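Islets of adult mice were cultured overnight, dissociated with trypsin and sorted by fluorescence, and RNA was extracted with Trizol and made into libraries with a TruSeq RNA kit, per the labels' protocols. The authors deposited a single table with 1 column of RPKM values per library and 46959 rows, and every column was matched to a library by its title. STAR 2.5, featureCounts and edgeR 3.14.0 with the build GRCm38.p4 are listed per the submitters' processing notes, with no order or settings. The annotation release, the filters and the treatment of reads that map to several places are not given in the sources used here. RPKM divides reads by gene length and by the library's total, so a gene that takes a large share of a library lowers the values of all others: Ins2 held 12% and 12.4% of summed RPKM in the immature and 33.2% and 34.8% in the mature libraries, and Gcg 40.3% and 38.9% in the double negative libraries.

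Depth was recovered from the RPKM steps, using exonic gene lengths of the GENCODE M21 annotation of GRCm38. Within a tolerance of 0.02 reads, between 78.1% and 83.8% of low values (under 200 reads) were whole reads per library, and 74.2% of genes above 0 were whole in all 6 libraries. Coordinates are from the same annotation. Of 13 mitochondrially encoded protein genes, 5 are listed at 0 in every library, so a value of 0 can be a failed estimate. Read floors and Poisson bounds, with a 95% level, cover counting error only.

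Groups and replicate numbers were taken from the sample titles. The labels give male for replicate 1 and female for replicate 2, while the design text names pools of females only. The labels do not say that a replicate number marks a shared pool. Nothing shows how separate the pools were, so p-values measure only the spread between these libraries.

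Genes with an RPKM of at least 1 in at least 2 of the 6 libraries were tested on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, in a model of group means over all 6 libraries with an intensity trend, 3 residual degrees of freedom before moderation and Benjamini-Hochberg adjustment at 0.05. Differences on this scale understate the change of low genes. The model assumes one spread per gene, although the SD of the difference between replicates was 0.393 in immature, 0.132 in mature and 0.222 in double negative cells. Sex labels were tested with group as a covariate and 2 residual degrees of freedom. Gene lists were tested with limma's camera at an inter-gene correlation of 0.01 where at least 3 members were tested. Camera compares a list with all other tested genes, so a set called lower or higher is so relative to these. The median log2 difference of all tested genes was 0.285 for immature against mature and -0.084 for mature against double negative cells. It was 0.237 for immature against double negative cells. Of 19 lists, 14 passed for immature against mature, 12 for mature against double negative and 8 for immature against double negative cells, and 0 passed with an estimated correlation in any of the 3 comparisons. An estimated correlation leaves little power with 3 residual degrees of freedom. Even the endothelial list, with 12 of 12 members higher in immature than in mature cells, then had a limma camera adjusted p = 0.124. A list that did not pass that version is therefore undecided by it.

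The 20 gene lists, the tests, the alternatives and the rule for naming genes were set before the data were examined, and the alternatives added later are named as such. The rule took Ins1 and Ucn3, then the 12 largest rises and 12 largest falls between immature and mature cells (6 and 6 for the other pairs) among genes past the threshold, with a mean of at least 5 RPKM in the higher group and one direction in both replicates, and then up to 4 members of each list with the largest differences. Further list members were named for their known role after the values were seen, some of which did not pass. Predicted genes and pseudogenes were passed over. Results for some list members are not reported.

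The procedure was tested on simulated data with 200 changed genes at the real depths. Every simulated library took its spread beyond counting from the mature replicates (log2 SD 0.093), and all other genes were unchanged. The shares of false calls hold for that setting and are not error rates of the real calls. For immature against mature cells (8740 genes), 34.3%, 71.6% and 92.3% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and 53 of 184 calls were false. For mature against double negative cells (8727 genes) the shares were 25.4%, 61.2% and 90.9%, with 2 false of 120 calls. For immature against double negative cells (8720 genes) they were 38.8%, 80.6% and 93.9%, with 65 false of 207. For the sex labels (8745 genes) they were 31.8%, 77.6% and 87.9%, with 0 false of 131. Limma's voom was added to the simulation after these false calls were seen, and gave 12, 6, 24 and 14 false calls in the same order. Limma-trend stayed the main test, as it was fixed beforehand.

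Alternatives varied the pseudocount, the filter, the scaling, the trend, the groups in the fit, the replicate block, the list test and each left-out library. Added after seeing the data were voom on the recovered reads, genes with whole reads alone, reads thinned to one depth and a crossed block. Dilution of beta cell RNA was examined in 3 ways, the later ones made after the first had decided nothing, and all 3 are reported.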

Results

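Gene expression was measured by RNA sequencing in 3 populations of cells sorted from adult mouse islets, with 2 libraries per population and 6 libraries in all. The mice carried an Ins1-driven nuclear mCherry reporter, which marks cells that have made insulin, and a Ucn3-driven eGFP reporter, which marks mature beta cells. Cells positive for mCherry alone were called immature beta cells, cells positive for both reporters mature beta cells, and cells negative for both double negative, which are the non-beta islet cells. Each library came from pooled islets, and replicates 1 and 2 carry the sex labels male and female. The immature libraries were the shallowest: the RPKM steps of low genes correspond to 2393840 and 3448925 reads in the immature, 23718087 and 26824377 in the mature and 22063879 and 22731662 in the double negative libraries. A single read in a 1-kb gene was therefore worth 0.4177 and 0.2899 RPKM in the immature libraries and between 0.0373 and 0.0453 RPKM in the others. The log2(RPKM + 1) values of replicates correlated across genes at Pearson's r = 0.9672 for immature, 0.9973 for mature and 0.9905 for double negative cells, and genes are not independent replicates.

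The genes behind the sort, Ins1 and Ucn3, were lower in immature than in mature cells and higher than in double negative cells. Ins1 (ENSMUSG00000035804.5, chromosome 19, 52264297 to 52265476, plus strand, GRCm38), which encodes insulin, stood at 11992.31 and 13388.57 RPKM in the immature libraries, 46605.51 and 49446.95 RPKM in the mature and 335.68 and 735.21 RPKM in the double negative libraries. Ucn3 (ENSMUSG00000044988.7, chromosome 13, 3940688 to 3945349, minus strand, GRCm38), which encodes the peptide urocortin 3, stood at 20.35 and 31.78 RPKM in the immature, 93.85 and 97.71 RPKM in the mature and 1.07 and 2.83 RPKM in the double negative libraries. The immature Ucn3 values rest on 72 and 162 reads. Ucn3 fell by 1.87 (SE 0.32) from mature to immature cells, which were sorted as negative for its reporter, and it lay 3.23 (SE 0.32) above double negative cells. Relative to Ins1, Ucn3 differed between immature and mature cells by 0.05 (SE 0.43, limma adjusted p = 0.943).

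The first comparison asked how immature beta cells differ from mature beta cells. Genes of mature beta cell function were lower in immature cells. Of 13 tested beta maturity genes, 10 fell, 2 rose and 1 did not pass (11 lower and 2 higher adjusted over the list alone), and the rise of the nuclear receptor gene Esrrg by 0.38 turned sign under quantile normalization. Mafa, a transcription factor that drives insulin transcription, averaged 25.5 ± 17.5 RPKM in immature and 122.5 ± 0.152 RPKM in mature cells (SD, n = 2 libraries each). G6pc2, an islet glucose-6-phosphatase, fell by 2.26 on the log2 scale (SE 0.33), from 1753 to 366.4 RPKM, Ero1lb, an oxidoreductase of proinsulin folding, by 1.89 (SE 0.12), and the glucose transporter gene Slc2a2 by 1.21 (SE 0.19). Gipr, the receptor for the incretin GIP, rose by 1.06, and the GLP-1 receptor gene Glp1r measured 60.81 RPKM in immature and 74.86 RPKM in mature cells with a limma adjusted p = 0.0587. The list was lower as a set by limma's camera (median log2 difference -1.21, adjusted p = 3.48e-06), with an adjusted p = 0.249 with an estimated correlation. In the same immature libraries the macrophage gene Lyz2 averaged 167.2 RPKM, against 0.236 RPKM in mature cells.

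Among 16 beta identity genes, 11 fell, 3 rose and 2 did not pass, with the same counts adjusted over the list alone, and the rise of Slc30a8, a granule zinc transporter, by 0.23 turned sign under median-ratio rescaling. Ins1 fell by 1.92 (SE 0.35) on the log2 scale, and Ins2 by 1.81 (SE 0.35), a difference that quantile normalization removes by construction, since Ins2 is the highest gene of each of these libraries. The fall was 1.68 (SE 0.26) for Pcsk1, a prohormone convertase, and Pdx1 and Nkx6-1, transcription factors that maintain beta cells, fell by 0.77 and 0.67. Rfx6, a transcription factor of endocrine cells, rose by 1.69 (SE 0.07), from 8.435 to 29.49 RPKM, and it averaged 22.19 RPKM in double negative cells. Pax6 and Neurod1, general endocrine transcription factors, differed by 0.02 and -0.11, with limma adjusted p = 0.859 and 0.0967. The set was lower (median -0.61, limma camera adjusted p = 8.08e-05), with adjusted p = 0.17 with an estimated correlation, and it did not pass after quantile normalization. The endothelial cadherin gene Cdh5 moved the opposite way in these libraries, at 125.1 RPKM against 0.3795 RPKM.

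**Figure D1:**
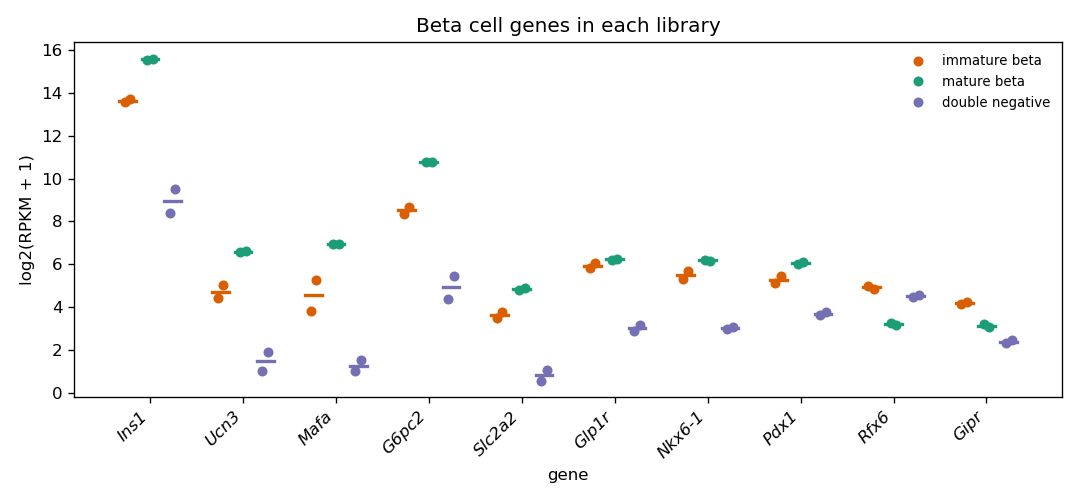
log2(RPKM + 1) of 10 beta cell genes, with a point for each library and a bar for the mean of the 2 libraries of a group. Ucn3 and Mafa lie lowest in the double negative, intermediate in the immature and highest in the mature libraries, while Rfx6 and Gipr lie higher in the immature than in the mature libraries.

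Genes of stimulus-secretion coupling divided. Of 23 tested, 13 fell, 5 rose and 5 did not pass, also adjusted over the list alone, and the rise of the calcium channel subunit gene Cacnb2 by 0.35 turned sign under quantile normalization. Atp2a3 and Atp2a2, calcium pumps of the endoplasmic reticulum, fell by 1.36 and 1.31 (SE 0.06 and 0.05), and the syntaxin gene Stx1a rose by 1.24 (SE 0.06), to 11.44 RPKM against 12.7 RPKM in double negative cells. The set was lower (median -0.33, limma camera adjusted p = 8.37e-05), with adjusted p = 0.188 with an estimated correlation. Of 15 endoplasmic reticulum stress genes, 13 fell, 1 rose and 1 did not pass, again also adjusted over the list alone. The pseudokinase gene Trib3 fell by 1.49 (SE 0.06), from 106.8 to 37.41 RPKM, and the chaperone cofactor genes Creld2 and Dnajb9 by 1.12 and 1.02, while the stress transcription factor gene Atf3 rose from 12.89 to 27.17 RPKM. This set was lower by limma's camera (median -0.62, adjusted p = 2.4e-09), with adjusted p = 0.123 with an estimated correlation. Nuclear genes of oxidative phosphorylation fell in 12 of 21 cases and none rose, also adjusted over the list alone, with Cox5a, a subunit of cytochrome c oxidase, down by 0.47 (SE 0.09). Their median was -0.24 (limma camera adjusted p = 2.08e-07), with adjusted p = 0.186 with an estimated correlation. Among 7 tested mitochondrially encoded genes, mt-Co1 and mt-Cytb fell by 0.33 and 0.29 and 5 did not pass, and none passed adjusted over the list alone. That set had a limma camera adjusted p = 0.0108, with adjusted p = 0.403 with an estimated correlation, and it did not pass with fry or without immature replicate 1. Acinar transcripts moved the other way in the same libraries, with Ctrb1 at 3705.49 and 13423.46 RPKM.

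All 19 genes of the list kept low in beta cells, called disallowed genes, rose in immature cells, also adjusted over the list alone. Ldha, which makes lactate from pyruvate, rose by 1.60, the hexokinase gene Hk1 by 3.01, the lactate transporter gene Slc16a1 by 1.99, and Arhgdib, abundant in blood cells, by 4.47 (SE 0.08), from 0.0356 to 21.98 RPKM. The set rose by limma's camera (median 2.27, adjusted p = 1.42e-06), with adjusted p = 0.123 with an estimated correlation. Of 13 tested precursor and immaturity genes, 11 rose and 2 fell, also adjusted over the list alone, and 3 of the rises (Neurog3, Aldh1a3 and Gast) turned sign under quantile normalization. The retinol-binding protein gene Rbp4 rose by 3.80 (SE 0.10), from 9.954 to 151.4 RPKM, Fev, a serotonergic transcription factor, by 2.52, and the Notch target Hes1 by 2.41, whereas the peptide gene Npy fell by 1.92. The set had a limma camera adjusted p = 0.0447, with adjusted p = 0.249 with an estimated correlation, and it also did not pass at 5 RPKM, without the trend, with voom, with whole-read genes or after thinning. The immune gene Tyrobp measured 107.9 RPKM in immature and 0.0748 RPKM in mature cells, beside both of these groups.

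Markers of other pancreatic cell types were higher in the immature than in the mature libraries. All 11 tested immune genes rose, with Lyz2 up by 7.09 (SE 0.09), the complement gene C1qb by 6.88 and the MHC class II gene H2-Aa by 6.71. All 12 endothelial genes rose, with Cdh5 up by 6.52 (SE 0.09) and Plvap, a protein of capillary diaphragms, by 6.24. Of 11 mesenchymal genes 10 rose and 1 did not pass, with the matrix proteoglycan gene Dcn up by 5.41 (SE 0.28). These counts were the same adjusted over the list alone. The limma camera adjusted p was 1.57e-06 for immune, 1.02e-06 for endothelial and 0.000631 for mesenchymal genes, and the adjusted p = 0.123, 0.124 and 0.139 with an estimated correlation.

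Hormone genes of the other endocrine cells rose as well. All 12 alpha cell genes rose, with the glucagon gene Gcg at 28018.13 and 19011.8 RPKM against 531.96 and 722.83 RPKM in mature cells and the rise of Dpp10 turning sign under quantile normalization. All 5 tested delta cell genes rose, with the somatostatin gene Sst up by 3.68 (SE 0.20) and the regulator Hhex by 3.03, and Ptprz1 turned sign under quantile normalization. All 3 PP cell genes rose, with the peptide hormone genes Pyy and Ppy up by 5.67 and 5.54. The counts were the same adjusted over the list alone. The limma camera adjusted p was 0.000861 for alpha, 0.0143 for delta and 0.0247 for PP cell genes, and the adjusted p = 0.344, 0.288 and 0.2 with an estimated correlation.

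Of 12 tested acinar genes, 11 rose and 1 fell, also adjusted over the list alone, yet the set test gave a limma camera adjusted p = 0.111. The colipase gene Clps rose by 7.23 (SE 1.10) and the trypsinogen gene Prss2 by 6.81, while Bhlha15, a secretory transcription factor, fell by 0.99. Median acinar expression was 486 and 1390 RPKM in the immature libraries, 9.12 and 6.3 RPKM in the mature and 13.8 and 132 RPKM in the double negative libraries. Ductal genes rose in 5 of 8 cases and fell in 2, also adjusted over the list alone, with the tetraspanin gene Tspan8 up by 3.78, the keratin gene Krt19 up by 2.38, and the phosphoprotein gene Spp1 down by 1.45 (limma camera adjusted p = 0.826). Glial genes rose in 3 of 4 cases, also adjusted over the list alone, with the neurotrophin receptor gene Ngfr up by 2.96 (limma camera adjusted p = 0.244). Cell cycle genes rose in 5 of 9 cases (6 adjusted over the list alone), with the replication helicase genes Mcm3 and Mcm6 up by 2.22 and 1.47 and Rrm2 turning sign under quantile normalization (limma camera adjusted p = 0.423). Early response genes, which cell dissociation can induce, rose in 12 of 16 cases and fell in 1, also adjusted over the list alone, with Klf6 up by 2.60 and Zfp36 by 1.89 (limma camera adjusted p = 0.0515).

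**Figure D2:**
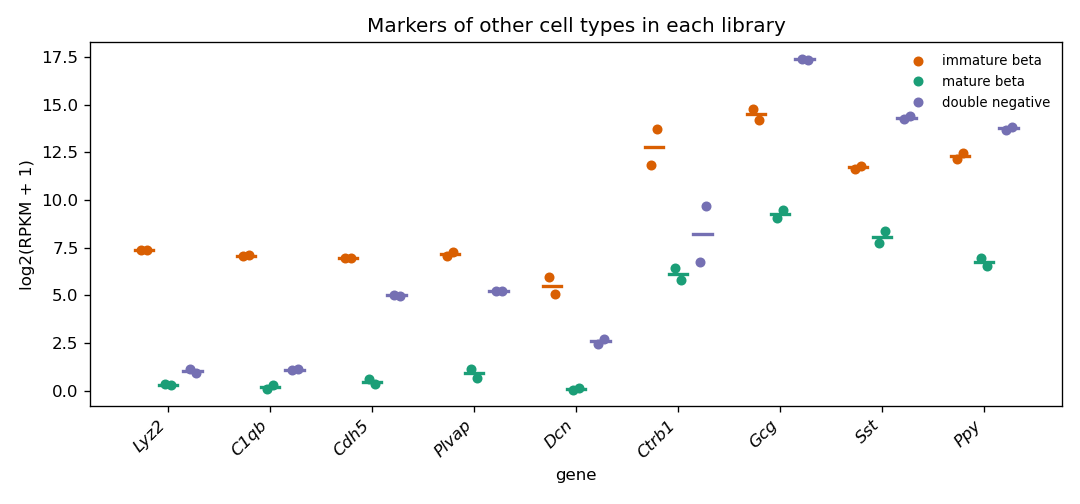
log2(RPKM + 1) of 9 marker genes of immune, endothelial, mesenchymal, acinar, alpha, delta and PP cells, with a point for each library and a bar for the mean of the 2 libraries of a group. Lyz2 and C1qb are high in the immature libraries alone, and Gcg, Sst and Ppy lie between the mature and the double negative libraries.

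The 12 named genes with the largest rises were Ctss, Cd74, Apoe, Esm1, Clps, Thbs1, Lyz2, Tgfbi, Cyp1a1, C1qb, Try4 and Mpeg1. The lysosomal protease gene Ctss rose by 7.84 (SE 0.08, limma adjusted p = 4.29e-07), from 0.2614 to 287.9 RPKM, and the MHC class II invariant chain gene Cd74 by 7.81 (SE 0.09). Cyp1a1, a xenobiotic-metabolizing enzyme, measured 176.6 RPKM in immature, 0.4327 RPKM in mature and 36.68 RPKM in double negative cells. The 12 largest falls were of S100a9, Nptx2, Ttyh1, Mir132, Tmem215, Angptl7, Lcn2, S100a8, Dusp14, Mafa, Ovol2 and G6pc2. The calcium-binding protein gene S100a9 fell by 3.38 (SE 0.27, limma adjusted p = 0.000149), from 77.91 to 6.844 RPKM, and the neuronal pentraxin gene Nptx2 by 2.94 (SE 0.10). The chloride channel gene Ttyh1 measured 16.9 and 16.86 RPKM in immature and 115.97 and 116.32 RPKM in mature libraries. Mir132, a microRNA gene with 0 and 4.39 RPKM in the immature libraries, lost its call in 5 alternative fits, and 3 reads would give 19 and 13.2 RPKM there against 14.05 and 13.56 RPKM in the mature libraries, so this fall is not resolved.

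In total 8728 of 13367 tested genes passed limma at an adjusted p under 0.05, 6655 higher and 2073 lower in immature cells, of which 2543 and 287 differed by at least 1 on the log2 scale. The share of higher genes was 76.2% with the deposited scaling, 44% after median-ratio rescaling (3930 higher, 5001 lower) and 36.8% after quantile normalization (3122 higher, 5359 lower), as the median difference of all genes moved from 0.29 to -0.09 and -0.17. Voom on the recovered reads, which covers only genes with whole reads, called 5639 genes here, where limma on those genes called 5860. In simulated data with only 200 changed genes at these depths, 53 of 184 calls (28.8%) were false. That share does not carry over to the real counts, where far more genes passed.

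**Figure D3:**
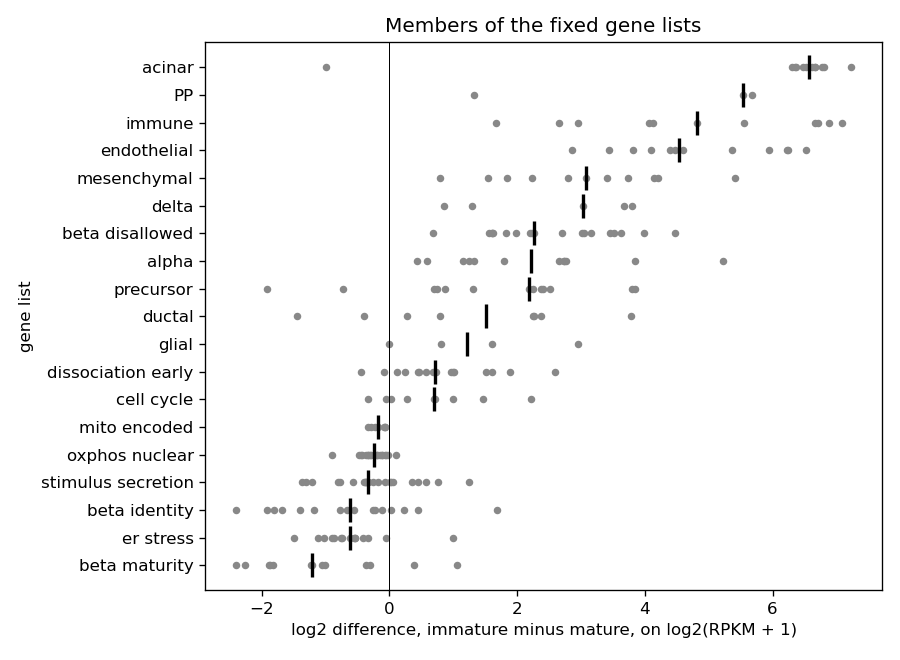
Difference in log2(RPKM + 1), immature minus mature, for each tested member of 19 fixed gene lists (points) and the list median (bar). The beta maturity median lies lowest at -1.21 and the acinar median highest at 6.57.

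The second comparison set mature beta cells against double negative cells. Beta cell genes were higher in mature cells: 12 of 13 beta maturity genes rose and 1 fell, and 11 of 16 beta identity genes rose and 4 fell, in both cases also adjusted over the list alone. Ins2 rose by 6.64 (SE 0.35) and Ins1 by 6.59 (SE 0.35), G6pc2 by 5.84, Mafa by 5.66, Tmem215 by 5.41 and Pcsk1 by 5.28. Ucn3 rose by 5.10 (SE 0.32, limma adjusted p = 7.63e-05). The limma camera adjusted p was 1.53e-07 for beta maturity and 0.00165 for beta identity genes, with adjusted p = 0.2 with an estimated correlation for both. Secretion coupling genes rose in 12 of 23 cases and fell in 6 (13 and 6 adjusted over the list alone), with Slc2a2 up by 4.02 (limma camera adjusted p = 0.0241), and the adjusted p = 0.304 with an estimated correlation. Endoplasmic reticulum stress genes rose in 13 of 15 cases and none fell, also adjusted over the list alone, with Trib3 up by 2.66 (SE 0.06) and Ddit3, a stress-induced transcription factor, by 1.86 (limma camera adjusted p = 1.72e-07), and the adjusted p = 0.177 with an estimated correlation. Nuclear oxidative phosphorylation genes rose in 11 of 21 cases, also adjusted over the list alone, with Cox5a up by 1.09 and Ndufa4 and Atp5b turning sign under quantile normalization (limma camera adjusted p = 0.00061), and the adjusted p = 0.283 with an estimated correlation. Mitochondrially encoded genes passed in 1 of 7 cases, mt-Co1 with a rise of 0.35, and in none adjusted over the list alone (limma camera adjusted p = 0.153).

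Genes of the other islet cells were lower in mature cells, and the double negative libraries held the endothelial gene Cdh5 at 30.91 RPKM beside the endocrine genes. All 12 alpha, 5 delta and 3 PP cell genes fell, also adjusted over the list alone. Gcg fell by 8.09 (SE 0.24) to 627.4 RPKM. The log2 difference was -7.01 for Ppy, -6.72 for Pyy, -6.28 for Sst and -5.99 for Eef1a2, a translation elongation factor. The limma camera adjusted p was 1.14e-07 for alpha, 0.000252 for delta and 0.00226 for PP cell genes, and the adjusted p = 0.2, 0.2 and 0.177 with an estimated correlation. All 12 endothelial genes fell, also adjusted over the list alone, and 9 of 11 mesenchymal genes fell (10 adjusted over the list alone), with limma camera adjusted p = 1.14e-07 and 0.00102 and adjusted p = 0.177 with an estimated correlation for both. Disallowed genes fell in 15 of 19 cases, also adjusted over the list alone, with the IGF-binding protein gene Igfbp4 down by 4.29 (limma camera adjusted p = 9.02e-06), and the adjusted p = 0.177 with an estimated correlation. Precursor genes fell in 8 of 13 cases and rose in 2, also adjusted over the list alone, with Neurog3, the endocrine progenitor factor, down by 2.34 and Npy up by 4.86 (limma camera adjusted p = 0.0219), and the adjusted p = 0.2 with an estimated correlation.

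The remaining lists did not pass as sets by limma's camera. Immune genes rose in 1 of 11 cases and fell in 5, also adjusted over the list alone, with the lysosomal gene Cd68 at 42.21 RPKM in mature and 9.812 RPKM in double negative cells, H2-Aa down by 1.43, and the fall of Csf1r turning sign under quantile normalization (adjusted p = 0.184, limma camera). Acinar genes rose in 1 of 12 cases and 0 fell, also adjusted over the list alone. The gene that rose was Bhlha15, at 24.48 RPKM in mature and 11.38 RPKM in double negative cells. Clps differed by -2.89 (SE 1.10, limma adjusted p = 0.0705), and the set had a limma camera adjusted p = 0.279. Ductal genes rose in 2 and fell in 3 of 8 cases (4 adjusted over the list alone), glial genes fell in 3 of 4 cases, cell cycle genes rose in 2 and fell in 3 of 9, and early response genes rose in 6 and fell in 9 of 16. The light chain gene Igkc measured 0.08 and 0.14 RPKM in mature and 69.77 and 66.98 RPKM in double negative libraries, and its call was lost in 5 alternative fits. In total 7256 of 13367 genes passed limma, 3088 higher and 4168 lower in mature cells (42.6% higher, 52.7% after median-ratio rescaling and 52.4% after quantile normalization). The total was 4720 without mature replicate 2, where the lower genes numbered 2627, and the higher genes numbered 1980 without mature replicate 1.

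The third comparison set immature beta cells against double negative cells. Beta maturity genes rose in 11 of 13 cases and none fell (12 adjusted over the list alone), with G6pc2 up by 3.58 (SE 0.33), Ucn3 by 3.23 (SE 0.32), Prlr, the prolactin receptor gene, by 3.19 and Glp1r by 2.91 (limma camera adjusted p = 0.00223), and the adjusted p = 0.603 with an estimated correlation. Beta identity genes rose in 10 of 16 cases and fell in 3, also adjusted over the list alone, with Ins2 up by 4.83 and Ins1 by 4.67 (limma camera adjusted p = 0.616). Immune genes rose in all 11 cases, also adjusted over the list alone, with Lyz2 up by 6.37 (SE 0.09) and C1qb by 5.98. Outside this list Ctss rose by 6.30, Mpeg1, a perforin-like macrophage gene, by 5.88, the apolipoprotein gene Apoe by 5.83 and the acid phosphatase gene Acp5 by 5.52. Endothelial genes rose in all 12 cases, also adjusted over the list alone, with Eng, a TGF-beta co-receptor gene, up by 2.08 (SE 0.09), and mesenchymal genes in 10 of 11. The limma camera adjusted p was 7.72e-08 for immune, 2.79e-05 for endothelial and 0.0107 for mesenchymal genes, and the adjusted p = 0.153, 0.153 and 0.179 with an estimated correlation. Disallowed genes rose in 16 of 19 cases and fell in 2, also adjusted over the list alone, with Arhgdib up by 2.73 (limma camera adjusted p = 0.00813), and the adjusted p = 0.153 with an estimated correlation.

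Alpha, delta and PP cell genes were lower in immature than in double negative cells, and the macrophage gene Lyz2 stood at 167.2 RPKM beside them. All 12, 5 and 3 tested members fell, also adjusted over the list alone, with log2 differences of -2.88 (SE 0.24) for Gcg, -2.60 (SE 0.20) for Sst and -1.49 for the transcription factor gene Etv1. The limma camera adjusted p was 8.61e-14, 5.47e-07 and 0.00034, and the adjusted p = 0.153 with an estimated correlation for each. The neurotensin gene Nts fell by 3.15 (SE 0.14) and the imprinted gene Peg10 by 2.62 (SE 0.20). Ghrl, which encodes ghrelin, was listed at 0 in both immature libraries, where 3 reads would give 1.16 and 0.806 RPKM, against 3.86 and 8.24 RPKM in the double negative libraries. The immunoglobulin gene Ighv1-11 was also listed at 0 in both immature libraries, where 3 reads would give 3.57 and 2.48 RPKM, against 5.42 and 18.8 RPKM.

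Other lists did not pass as sets by limma's camera in this comparison. Acinar genes rose in 11 of 12 cases, also adjusted over the list alone, with Ctrb1 up by 4.57 (SE 1.04, limma adjusted p = 0.0121), and ductal genes rose in 3 and fell in 1 of 8, with Krt19 up by 2.19 and Krt7 turning sign under rescaling. Precursor genes rose in 7 and fell in 4 of 13 cases, with Npy up by 2.94 and Rbp4 down by 1.92. Secretion coupling genes rose in 8 and fell in 4 of 23 cases, with Atp2a3 and Unc13a turning sign under rescaling, and stress genes of the endoplasmic reticulum rose in 7 and fell in 3 of 15, with Creld2 and Atf4 turning sign under median-ratio rescaling or quantile normalization. Cell cycle genes rose in 6 of 9 cases, glial genes rose in 3 and fell in 1 of 4, and early response genes rose in 8 and fell in 4 of 16. Nuclear oxidative phosphorylation genes rose in 3 and fell in 3 of 21 cases, with Sdhb turning sign under rescaling, and none of 7 mitochondrially encoded genes passed. Adjusted over the list alone, oxidative phosphorylation genes rose in 2 cases and fell in 2, and the other counts of this paragraph stayed. In total 7563 of 13367 genes passed limma, 6142 higher and 1421 lower in immature cells (81.2% higher, 48.7% after median-ratio rescaling with 3362 higher and 3545 lower, and 39.7% after quantile normalization with 2864 higher and 4348 lower). Voom on the recovered reads called 4841 genes, where limma on the same whole-read genes called 5101. In simulated data with only 200 changed genes, 65 of 207 calls (31.4%) were false, a share that does not carry over to the real counts.

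Immature cells were also placed between the other populations, on a scale where 0 is the mature and 1 the double negative level of the same replicate number. Over the 715 genes higher in mature cells the median position was 0.503 in replicate 1 and 0.471 in replicate 2. Over the 1194 genes higher in double negative cells it was 0.932 and 0.929, and 46.9% and 46.5% of these genes lay beyond the double negative level. Rfx6 and the immune gene Ctss are examples beyond it, at 29.49 and 287.9 RPKM in immature against 22.19 and 2.66 RPKM in double negative cells. These 2 values per gene group were not tested, and the second median ranged from 0.592 to 1.244 over the alternatives.

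The sex labels were compared with cell group as a covariate, over 3 libraries labelled male and 3 labelled female. Xist, the X-inactivation RNA expressed in females, measured 129, 36.5 and 38.9 RPKM in the immature, mature and double negative libraries labelled male, and 108, 21.4 and 47.6 RPKM in those labelled female. The highest Y-linked value among Ddx3y, Kdm5d, Uty and Eif2s3y was 0.161 RPKM in the libraries labelled male and 2.23 RPKM in those labelled female, the latter for Eif2s3y in an immature library. Eif2s3y had 1, 0 and 0 reads in the immature, mature and double negative libraries labelled male, and 32, 13 and 4 in those labelled female. No direction by sex is drawn from these labels. At an adjusted p under 0.05, 0 of 13367 genes passed limma, 228 had an unadjusted p under 0.05, and 19 passed with voom on the recovered reads. The count was 9 without immature replicate 1, 7 without immature replicate 2, 7 without mature replicate 1 and 4 without mature replicate 2. The label coincides with the replicate number, and with Xist at these levels in every library labelled male the contrast compares replicates.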

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

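Predictions for the thinning and for the splits of the libraries were written before those results were seen, and all other tests in this part were chosen after the result was seen. Acinar genes differed between replicates in opposite directions in different cell groups. The median log2 difference, library labelled female minus library labelled male, was 3.05 in double negative cells, where 11 of 12 members were higher, and -0.42 in mature beta cells, where 0 of 12 were higher. It was 1.5 in immature cells. The difference between groups was not tested, since each value rests on 1 library per label.

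Markers of immune, endothelial, mesenchymal, acinar, alpha, delta and PP cells were high in the immature libraries. Lower depth as the cause is argued against by thinning all libraries to one depth, after which the median immune difference from mature cells was 2.96 over the 5 members with whole reads (SD 2.09, lowest 1.67). Carry-over of the double negative mixture as a single source is argued against by list medians of log2(immature/double negative) that differ by 8.51, from 6.28 for immune to -2.23 for alpha cell genes. Separate admixtures of whole cells remain open and may account for part of the pattern, although the mCherry gate would remove cells without the reporter. The 12 endothelial genes kept close to a single ratio, with an SD of 0.19, and the test was set for this list alone. The SD was 1.44 for immune, 1.26 for mesenchymal, 1.09 for acinar, 0.6 for alpha, 0.36 for delta and 0.28 for PP cell genes. Some lists held members that were not low in mature cells, which can widen their SD. The acinar list included Bhlha15, at 11.89 RPKM in immature, 24.48 RPKM in mature and 11.38 RPKM in double negative cells. The immune list included Cd68, at 42.21 RPKM in mature cells. The wider SDs therefore do not settle whether markers of those cell types kept a constant ratio. Expression by the immature beta cells themselves cannot be told apart from such admixtures. By limma's camera 6 of 7 lists of other cell types were higher at the preset correlation (0 with an estimated correlation). Bulk values do not say which cells held the RNA.

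Beta cell genes were lower in the immature libraries, and dilution by other RNA could lower them with no change within beta cells. Of 79 genes high in mature and low in double negative cells, 78 had an annotated length, Ins1 itself among them. Of these 78, 6 (7.69%) lay below the Ins1 level in both libraries beyond counting error and 32 lay above it. Bounds of 5% and 10% had been set for the share below, so it decided nothing. Of 3 analyses of this question, the other 2 were made after that value was seen. Relative to Ins1, limma tested the 78 genes other than Ins1, whether or not they had a length. It found 1 lower (S100a9, adjusted p = 0.034) and 7 higher (among them Glp1r by 1.62, Bace2 by 1.23 and Iapp by 0.52), with a median SE of 0.54. The median level over all 79 was 31.9% and 35.2% of mature against 25.7% and 27.1% for Ins1. Counts of 6 below and 32 above are not those of a single ratio shared by all genes. Counting error leaves out the spread between libraries, however. In the fit relative to Ins1, which includes the spread between libraries of all 3 groups, 70 of 78 genes did not pass. None of the 3 decided, so dilution and a lower expression in immature beta cells cannot be told apart. By construction the spread of Ins1 between replicates enters the SE of every gene in that fit. This spread was widest in the double negative libraries (335.68 and 735.21 RPKM), which are not part of the comparison. Ins1 was closer between the immature libraries (11992.31 and 13388.57 RPKM) and between the mature libraries (46605.51 and 49446.95 RPKM). The genes that did not pass are therefore no evidence for a single ratio.

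The sex labels and the sex-linked genes disagreed, and a wrong label on the libraries labelled male may be the cause: their lowest Xist value was 36.5 RPKM and their highest Y-linked value 0.161 RPKM. In each cell group the few reads of Ddx3y and Eif2s3y lay mostly in the library labelled female. The design text names females, and no biological explanation was tested. The sex labels gave 0 genes by limma at an adjusted p under 0.05 (228 at an unadjusted p under 0.05, 19 by voom), so the 10 of 10 splits of the libraries with at least that many genes say nothing about chance. The highest other count was 1382, in the 2 splits that divide the immature libraries and no other group.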

How the results depend on the processing

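The voom, whole-read, thinned and crossed-block fits were chosen after seeing the data. Ins1, Ucn3 and the genes named for the largest rises and falls of each comparison kept their direction. So did the list medians of immature against mature cells, and list medians of the other pairs were not run under the alternatives. In all 3 comparisons of cell groups, however, the balance of higher and lower genes and the sign of the median difference turned under either rescaling. Some single list members turned under only 1 of them, such as Slc30a8 under median-ratio rescaling and Esrrg and Cacnb2 under quantile normalization. Over all alternatives 833 values of named genes kept their side of the threshold and 12 did not, for Mir132, Igkc, Ins1 and Gcg. The lists of immature against mature cells kept their side in 309 cases, gained a pass in 20 and lost it in 22. The counts kept within 1.5 times their value except as given here, and the cause was not tested unless stated.

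Median-ratio rescaling gave 3930 higher and 5001 lower genes for immature against mature cells and 3362 and 3545 for immature against double negative cells, and quantile normalization gave 3122 and 5359, and 2864 and 4348: both shift all genes of a library. A minimum of 5 RPKM tests fewer genes and left 4118 higher in immature than in mature cells. By limma's camera 0 of 14 lists stayed with an estimated correlation, a version with little power at 3 residual degrees of freedom. The other losses were of the precursor, beta identity and mitochondrially encoded lists, and the gains of the acinar, early response, ductal, glial and cell cycle lists, the last 3 with fry alone. Voom on the recovered reads, over fewer genes, gave 5639 (1182 lower) for immature against mature, 4841 (4078 higher, 763 lower) for immature against double negative cells and 19 for the sex labels, and whole-read genes gave 4773 (2711 lower) for mature against double negative cells. Thinning to the shallowest library, which also keeps only genes with whole reads, left 4364 (3422 higher, 942 lower), 3335 (1484, 1851) and 3253 (2724, 529) for the 3 pairs in the report's order, against 5860, 4773 and 5101 with whole-read genes at full depth.

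The position of genes higher in mature cells was 0.487 as the mean of the replicates, 0.415 and 0.46 with pseudocounts of 0.1 and 0.5, 0.701 after median-ratio rescaling, 0.692 after quantile normalization and 0.436 at a log2 difference of at least 2. For genes higher in double negative cells it was 0.931, and in the same order 1.244, 1.068, 0.766, 0.592 and 0.812, with 0.925 without a filter, 1.092 at 5 RPKM, 0.913 with whole reads and 0.887 after thinning.

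Leaving out 1 library, where the lone library of a group is assumed to vary like the others, gave from 1283 (without mature replicate 1) to 2468 lower genes for immature against mature cells. For mature against double negative cells it gave from 4720 (without mature replicate 2) to 8657 genes, 1980 (without mature replicate 1) to 3787 higher and 2627 (without mature replicate 2) to 4872 lower. For immature against double negative cells it gave from 5016 (without double negative replicate 1) to 7910 genes and 767 (without that library) to 1902 lower. The sex labels gave 0 to 9 (without immature replicate 1), and the second position 0.92 to 1.056.

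With the replicate number as a block the counts were 8407, 6803 and 7073 for the 3 pairs, and 16 lists. Deviations of libraries with the same number correlated at -0.009, 0.14 and -0.112, so the number was not taken as a pairing. A crossed block gave 7236 (3080 higher, 4156 lower) for mature against double negative cells.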

Other observations

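The genes in this part and the tests by scaling and thinning were chosen after the result was seen. In limma at an adjusted p under 0.05, 4168 genes were higher in immature cells than in both other populations and 365 were lower than in both, and the counts were 2197 and 2065 after median-ratio rescaling, 1822 and 2624 after quantile normalization and 1814 and 92 after thinning. Both comparisons share the immature libraries, so part of this overlap may come from shared values. Independent lists of these sizes would share 3058 and 220 genes. In 50 simulations with no difference between any groups, the mean was 0.06 genes in each direction. Without group differences few calls could arise, so these simulations do not measure the overlap that comes from shared libraries.

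Some single genes of secretory granules were lower in immature cells than in both populations under each scaling, and no test of them as a group was made. Dilution by other RNA in the immature libraries could also lower them and was not tested for these genes. Those libraries held, for example, the acinar gene Ctrb1 at 3705.49 and 13423.46 RPKM and the macrophage gene Lyz2 at a mean of 167.2 RPKM. Pam, which amidates peptides, averaged 114 RPKM in immature, 306 RPKM in mature and 197 RPKM in double negative cells (log2 differences -1.42 and -0.78). The convertase gene Pcsk2 averaged 350, 534 and 637 RPKM, its chaperone gene Scg5 518, 749 and 976 RPKM, and the neuropeptide gene Vgf 87.1, 327 and 154 RPKM. Other granule genes did not follow this: Chga differed from mature cells by 0.17 with a limma adjusted p = 0.145, and against double negative cells Chgb was higher by 1.54 and Scg3 by 0.41, while Scg2 differed by 0.16 with a limma adjusted p = 0.137.

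S100a8, S100a9 and Lcn2, known from neutrophils, were highest in mature cells, S100a9 at 77.9 RPKM against 6.84 RPKM in immature and 1.29 RPKM in double negative cells, and Lcn2 at 156, 28 and 20.8 RPKM. Nptx2 averaged 134 RPKM in mature and 16.7 and 16.8 RPKM in the other populations. Igkc differed between the immature libraries, at 113.07 and 3.27 RPKM.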
